A study of Mus musculus with 5 samples.

How the data were processed

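H3K23pr was measured by ChIP-seq in 4 pools of 3 mouse hearts each, 1 pool and 1 library per group: control diet with sham surgery, control diet with TAC, BCAA-free diet with sham surgery and BCAA-free diet with TAC. The labels also describe a pooled input library. No column of the table used here belongs to it, so it was not analysed here and no value is corrected for input. BWA, MACS2 and the genome build mm10 are named per the submitters' processing notes. Their versions and settings, the depth of each library in reads and any scaling between libraries are not given in the sources used here.

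A single deposited table was used, with 34346 merged regions whose boundaries lie on a 200-bp grid. Per the file headers it gives for each library the mean and the highest signal (coverage) of each region and whether the library has a called interval there. Every region was called in at least 1 of the 4 libraries. The authors also deposited log2 ratios of the mean coverage for the 4 comparisons. They were recomputed from the coverage columns without a pseudocount and were equal within rounding (largest difference 8.88e-16) in all cells that held a number, which left out 1 or 2 cells per comparison that held a spreadsheet error. A further deposited score, the larger tag number of the libraries compared, equalled mean coverage times region length divided by 224 bp in all 137384 cells, within a tolerance of 1e-06 bp on that length. Tag numbers per region were taken from that relation, which assumes that coverage is in unscaled fragments. The deposited table also lists the CpG islands, promoters and genes of each region, and gene names and regions are given as it gives them. All columns that belong to a library were matched to a sample, with 0 left unmatched.

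The change of a region was the log2 ratio of mean coverage plus a pseudocount of 1, which understates the change of regions with low coverage. A comparison used the regions called in at least 1 of its libraries, and a region was counted as higher or lower from 1.5-fold on, an exact tie included. With 1 library per group there is no test. The values describe these libraries. Because a region enters the table by being called in some library, regions of low coverage tend to enter through the library in which they are highest, which tilts their ratios. Depth in merged regions ran from 11677819 to 15110728 tags per library, and the median region had 159 to 197 tags in a library. The 95% intervals of tag ratios are exact binomial intervals. They cover counting error only, and fragments copied by PCR are not independent.

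A gene took the value of the region that lists it and is nearest to its start among the regions used in a comparison, so the region of a gene can differ between comparisons. For 27 gene lists (647 genes, each in 1 list) the median log2 ratio was placed among 10000 random gene lists of the same size, matched by decile of mean log2 coverage over the 4 libraries, and a list stood apart below percentile 2.5 or above 97.5. Of the 647 genes 624 were in the table, 7 of them under a synonym taken from a RefSeq table of assembly GRCm38.p6, and 23 were not. The lists cover sarcomere, hypertrophic stress, calcium handling and ion channels, fatty acid oxidation, glycolysis, TCA cycle, oxidative phosphorylation, BCAA catabolism, propionate metabolism, amino acid response, mTORC1 and autophagy, histone acylation writers and erasers, cardiac transcription factors, extracellular matrix and fibrosis, TGF-beta signalling, inflammatory cytokines, circadian clock, cell cycle, ribosomal proteins, heat shock and oxidative stress, angiogenesis and hypoxia, and markers of fibroblasts, endothelium, smooth muscle and pericytes, macrophages, lymphocytes and granulocytes, and adipocytes.

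Genes were named by a rule: for each comparison, among regions with a listed gene whose mean coverage over the 4 libraries was at or above the median of that mean among the regions of the comparison (8.52, 9.19, 9.62 and 8.42 for TAC on the control and the BCAA-free diet and for diet in sham and TAC hearts), the 10 with the largest rise and the 10 with the largest fall, 1 region per gene and without predicted genes. The mean includes the library in which a region is high, so a large rise in 1 library helps a region past this filter. The member with the highest and the lowest ratio of every list was added, as were Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Ttn, Col1a1, Postn, Bckdha, Bckdk, Pcca, Pccb, Atf4, Asns and Fgf21 wherever a region lists them. The groups, the comparisons, the measure, the lists, the naming rule and the first set of alternative settings were chosen before the data were examined. A few results that the rule names are not reported here. Other genes are said in place to have been named after their values were seen.

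The first set of alternative settings comprised the peak coverage, libraries rescaled to a median ratio of 1 over regions called in all 4 or to equal totals, pseudocounts of 0.1 and 5, all merged regions, regions called in all 4 libraries, a 2-fold threshold, other regions per gene and 20 coverage bins for matching. The following were added after the data had been seen: removal of the trend of the ratio on mean coverage (20 bins), the same removal within regions with and without a CpG island (10 bins each), promoter and CpG island subsets, and random lists matched on CpG islands as well. Settings that need the input were not run. For the overlap of effects, the number for independent lists is the product of both counts divided by the number of regions.

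The procedure was tested on simulated tag counts for the regions of the comparison of TAC with sham on the control diet (30508 regions, 27 lists). Every simulated library was drawn from the mean coverage of the 4 libraries with counting error only. Apart from the planted changes it held no difference between libraries, no trend on coverage and no variation between hearts. Its rates therefore do not hold for the real libraries. It recovered 94% of regions planted 2-fold higher and 92% of those planted 2-fold lower, and 0.38% of unchanged regions passed 1.5-fold. A list planted 1.4-fold higher came to percentile 100, and 0 of the 26 other lists stood apart. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.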

Results

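Propionylation of histone H3 at lysine 23 (H3K23pr), an acyl mark whose donor is propionyl-CoA, was mapped by ChIP-seq in hearts of male C57Bl/6J mice aged 12 weeks. The mice ate a control diet that contained branched-chain amino acids (BCAA) or a diet that lacked them, and both diets carried 1% propionate. Feeding began 4 days before sham surgery or transverse aortic constriction (TAC), an operation that narrows the aortic arch and overloads the left ventricle with pressure, and the hearts were taken 1 week after it. Each of the 4 groups was 1 library made from a pool of 3 hearts, so no difference given here has a replicate check, a test or a p-value. The pooled input library of the series was not analysed here.

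The deposited table held 34346 merged regions on mm10 with a median length of 4799 bp. A promoter lay in 13909 of them (40.5%), a CpG island in 11038 (32.1%), and at least 1 gene was listed for 26549 (77.3%). Tags in these regions came to 12797993 in the control-diet sham library, 13906143 in the control-diet TAC library, 11677819 in the BCAA-free sham library and 15110728 in the BCAA-free TAC library. In the same order, 22850, 27762, 20100 and 24111 regions were called by the authors. All 4 libraries shared 15417 called regions (44.9%), both TAC libraries alone shared 2317, and both sham libraries alone shared 1045. Across regions the log2 coverage of the sham libraries correlated at r 0.924 (Spearman 0.923), and the other 5 pairs of libraries lay between 0.677 and 0.757; regions are not independent replicates. The BCAA-free TAC library had the steepest peaks, with a 90th percentile of peak coverage of 149 against 79, 86 and 78 in the control-diet sham, control-diet TAC and BCAA-free sham libraries. It also had 66.8% of its tags in promoter regions, against 59.0%, 59.3% and 59.2%.

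Changes below are log2 ratios of mean coverage plus 1 on the deposited scale, and a region counts as higher or lower from 1.5-fold on. A gene is represented by the region that lists it and lies nearest to its start. A gene list is described by the distance of its median from the median of 10000 random lists of the same size and coverage, and by its percentile among them, which describes these libraries only.

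On the control diet, TAC hearts had more H3K23pr at extracellular matrix genes and less, relative to other genes of like coverage, at genes of fat oxidation, contraction and calcium handling. Col1a1, which encodes a chain of fibrillar type I collagen, rose 2.07-fold (log2 1.05), from a coverage of 6.84 in sham to 15.2 in TAC hearts. Postn, the gene of the matrix protein periostin made by activated fibroblasts, rose 1.96-fold (log2 0.97), from 4.78 to 10.3. Tnc (tenascin C, a matrix protein of wound repair) rose most in the matrix list, 2.90-fold (log2 1.54) from 2.09 to 7.98. Kcnip2, which encodes a subunit of the channel that carries the transient outward potassium current, fell by 0.95 on the log2 scale, from 14.6 to 7.05.

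The matrix list lay 0.40 above matched lists, at percentile 100. Of its 33 genes with a region (Col4a1 and Col4a2 share theirs), 17 rose and 0 fell. Besides Col1a1, Postn and Tnc these were Ltbp2 (1.20), Col12a1 (1.16), Timp1 (1.11), Fn1 (1.02), Lox (0.95), Thbs1 (0.95), Loxl2 (0.80), Mmp14 (0.75), Loxl1 (0.74), Col6a1 (0.72), Col1a2 (0.67), Bgn (0.64), Mmp2 (0.62) and Col6a2 (0.59). In this paragraph, members beyond Tnc, Col12a1, Col1a1 and Postn were named after their values were seen. Ltbp2 and Fn1 encode microfibril and adhesion proteins, and Lox encodes the enzyme that cross-links collagen. The tag ratio at the Col1a1 region (chr11:94925200–94960599, also listing Sgca and Hils1) had a 95% counting interval of 2.07 to 2.39, and that at the Postn region (chr3:54357200–54363199) one of 1.75 to 2.69.

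Among proliferation genes the cell cycle list lay 0.20 above matched lists (percentile 99.8), with Cdk1, the mitotic kinase, at 0.90. Mki67 (0.74), Top2a (0.65) and Tyms (0.61), named after their values were seen, also rose. In peak coverage this list came to percentile 96.0 and no longer stood apart. The ribosomal protein list lay 0.10 above matched lists (percentile 99.4), led by Rpl4 (0.59, and 0.46 after rescaling to equal median ratios), but at percentile 95.7 when all regions of a gene were averaged. Of the inflammatory genes, Il1b rose by 1.28 (2.95 to 8.62), and Il6 (1.22) and Ccl4 (1.04), named after their values were seen, rose as well. The inflammatory list as a whole lay 0.07 above matched lists, at percentile 85.9, and the macrophage list lay 0.15 above them, at percentile 95.1, with the Fc receptor gene Fcgr1 at 1.06. With the trend of the ratio on coverage removed, the macrophage list reached percentile 99.7 and Il1b (0.43) and Fcgr1 (0.48) changed less than 1.5-fold. The macrophage list also stood apart in peak coverage (percentile 98.0) and with a pseudocount of 5 (97.7), and the inflammatory list did with the strongest region of each gene (98.5).

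The fatty acid oxidation list lay furthest below matched lists, by 0.46 (a difference of -0.46, percentile 0), although none of its genes fell 1.5-fold. The sarcomere list differed from matched lists by -0.44, calcium handling and ion channels by -0.43, cardiac transcription factors by -0.31 (each at percentile 0), propionate metabolism by -0.27 (0.08), the TCA cycle by -0.19 (0.11), oxidative phosphorylation by -0.18 (0.02) and BCAA catabolism by -0.16 (0.75). These 8 lists stood apart on the low side under every alternative run. Adipocyte markers (-0.23, percentile 1.45), glycolysis (-0.17, percentile 0.38) and mTORC1 and autophagy genes (-0.12, percentile 1.13) stood apart as well, but not in peak coverage, where their percentiles were 3.64, 5.48 and 60.8. Csrp3, whose protein sits at the Z-disc, was the only sarcomere gene past the threshold (-0.66). Kcnd2 (-0.65, named after its value was seen), which encodes the channel that Kcnip2 modulates, fell too. The heart lactate dehydrogenase gene Ldhb changed by -0.65 and the ubiquitin ligase gene Trim63 by -0.64. With a pseudocount of 5 Csrp3 (-0.50), Ldhb (-0.48) and Trim63 (-0.43) stayed under 1.5-fold.

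Genes of the hypertrophic stress programme did not move together. Acta1 (skeletal actin) rose by 0.82 from 3.36 to 6.69, Nppa (atrial natriuretic peptide) by 0.67 and Nppb (brain natriuretic peptide) by 0.60. When libraries were rescaled to equal median ratios, Nppa (0.55) and Nppb (0.48) fell short of 1.5-fold, and with the trend on coverage removed Acta1 (0.24) did. Myh6 and Myh7, the myosin heavy chain genes, lie in a shared region (chr14:54936200–55011599) that changed by less than 1.5-fold (-0.52). Atp2a2, the calcium pump gene, changed by -0.27 and Ttn by -0.51. The hypertrophic stress list lay 0.03 above matched lists, at percentile 70.6.

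Of the 30508 regions called in either library, 5103 were higher and 1330 lower, and the median log2 ratio was 0.20. Higher regions made up 79.3% of those past 1.5-fold. Rescaling to equal median ratios shifted the median by -0.12 and gave 3504 higher and 2230 lower (61.1%). Rescaling to equal totals shifted it by -0.11 and gave 3686 and 2096 (63.8%), and removing the trend on coverage gave 1605 and 2912 (35.5%). Among the largest rises among regions past the coverage filter were those at Knstrn (a mitotic spindle gene, 1.46), Dusp27, Abr (1.34), Wdr95 (1.31), Mrc2 (a collagen receptor gene, 1.26), Tnr (1.21), Col12a1 (1.16), Anln (cytokinesis, 1.16) and Gpr176 (1.15). Among the largest falls were those at Wwox (-1.46), Pbld2 (-1.42), Chrna2 (-1.32), Arhgap1 (-1.24), Ltbp1 (-1.20), Asic2 (-1.14), Dhx35 (-1.13), Garnl3 (-1.12) and Oscar (-1.12). The Knstrn region (chr2:118813800–118814999) holds the promoter and went from a coverage of 4.76 to 14.8.

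**Figure D1:**
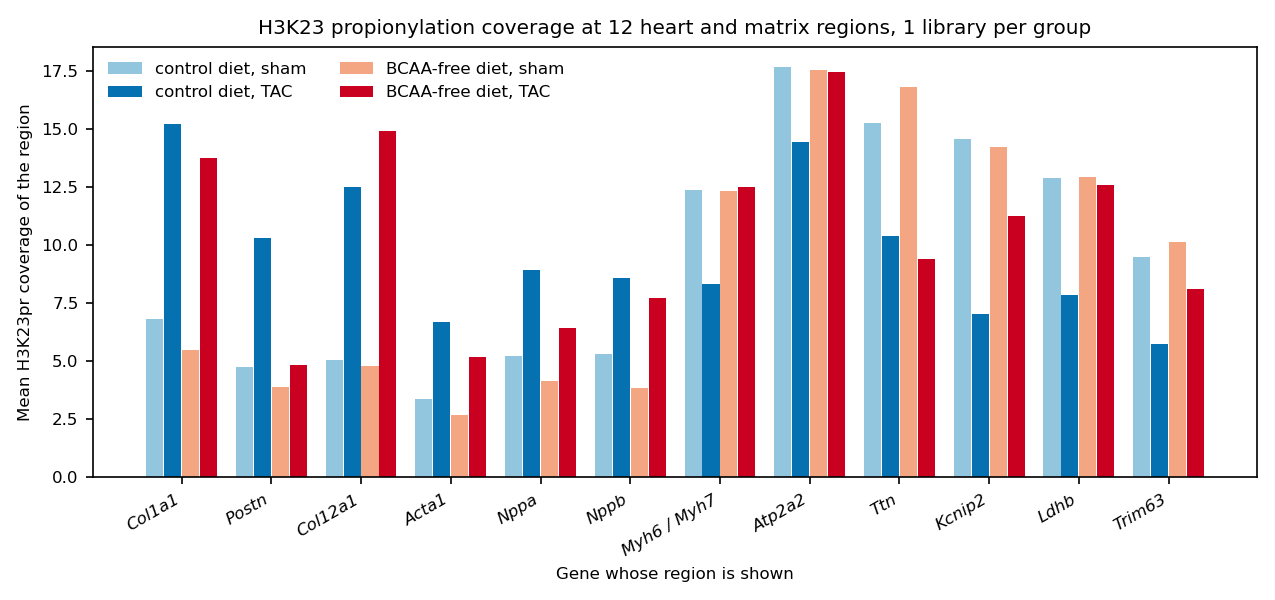
Mean H3K23pr coverage (y axis) of the regions of 12 heart and matrix genes (x axis), with a bar per group and 1 library behind each bar. Col1a1 stood at 6.84 and 15.2 in control-diet sham and TAC hearts and at 5.51 and 13.8 on the BCAA-free diet, while Postn stood at 4.78, 10.3, 3.91 and 4.86 in the same order.

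On the BCAA-free diet, TAC hearts had less H3K23pr, relative to other genes of like coverage, at genes of calcium handling and muscle structure, and more at macrophage genes and at CpG islands. Ryr2, which encodes the calcium release channel of the sarcoplasmic reticulum, fell by 0.89 on the log2 scale, from 14.4 to 7.33. Cd36, the gene of the fatty acid transporter, fell by 0.88, from 22.5 to 11.8, and Myoz2, a Z-disc gene, by 0.89. Col1a1 rose 2.27-fold (log2 1.18), from 5.51 to 13.8. Sfpi1, which encodes the myeloid transcription factor PU.1, rose 2.67-fold (log2 1.42), from 6.03 to 17.8.

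The calcium handling list lay furthest from matched lists, at -0.88 (percentile 0). Besides Ryr2, the phospholamban gene Pln (-0.83) and the junctional genes Trdn (-0.77) and Asph (-0.66), all 3 named after their values were seen, fell. Kcnh2, whose region also lists Nos3, rose by 0.78. The fatty acid oxidation list stood at -0.57 and the sarcomere list at -0.50, both at percentile 0. Not set against matched lists, the medians of these 3 lists were -0.25 (calcium handling), 0.09 (fatty acid oxidation) and 0.15 (sarcomere) as deposited, -0.60, -0.27 and -0.21 after rescaling to equal median ratios, and 0.26, 0.56 and 0.35 in peak coverage, so their direction depended on the scale and the measure. In the fatty acid oxidation list 2 of 29 genes rose and 2 fell. Ppargc1a, the coactivator of mitochondrial genes, changed by -0.69. The fatty acid enzyme gene Acads rose by 0.85, and by 0.50 after rescaling to equal median ratios. Among sarcomere genes Lmod2 (-0.79), Ttn (-0.78), Csrp3 (-0.76) and Actc1 (-0.60) fell, while Myl7 (0.80) and Tnnc1 (0.61) rose. Ppargc1a, Lmod2, Csrp3, Actc1 and Tnnc1 were named after their values were seen. Ttn, the gene of the giant elastic filament, went from 16.8 to 9.40 in mean coverage, but its peak coverage changed by 0.04.

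The TCA cycle list (-0.34, percentile 0.11), BCAA catabolism (-0.34, percentile 0.16), oxidative phosphorylation (-0.22, percentile 0.35), adipocyte markers (-0.37, percentile 1.32) and heat shock and oxidative stress (-0.20, percentile 2.27) also lay below matched lists. Each of these 5 returned inside the range under at least 1 alternative: averaging all regions of a gene put the TCA cycle at percentile 4.15 and oxidative phosphorylation at 2.58, and peak coverage put BCAA catabolism at 3.73 and heat shock at 9.87. Matching on CpG islands put adipocyte markers at 3.92. Bckdhb, which encodes a subunit of the dehydrogenase that commits BCAA to breakdown, fell by 1.15, from 10.2 to 4.05. The macrophage list was the only one on the high side, 0.35 above matched lists (percentile 99.7), with 18 of 21 genes up. The complement genes C1qa, C1qb and C1qc share a region that rose, and Csf1r (1.36), Itgam (1.22) and Aif1 (1.17), all named after their values were seen, rose too. In peak coverage the macrophage list came to percentile 90.4, and with the strongest region of each gene to 85.4. The matrix list lay 0.09 above matched lists (percentile 80.6) though 19 of its 29 genes rose, led by Col12a1 (1.45), and 0.30 above them in peak coverage (percentile 99.4).

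Of the 27641 regions called in either BCAA-free library, 10644 were higher and 2543 lower, with a median of 0.42, and higher regions made up 80.7% of those past 1.5-fold. This split depended on the scale. Rescaling to equal median ratios shifted the median by -0.34 and gave 4752 higher and 5322 lower (47.2%), and equal totals shifted it by -0.34 and gave 4861 and 5275 (48.0%). Removing the trend on coverage gave 3645 and 5372 (40.4%). Nppb (0.85, then 0.53), Myl7 (0.80, then 0.48), Kcnh2 (0.78, then 0.42), Bckdk (0.73, then 0.38) and Fgf21 (0.74, then 0.43) passed 1.5-fold as deposited and not after rescaling to equal median ratios. Relative to the median of all regions, CpG islands stood out: the median was 0.71 at promoters with a CpG island, 0.78 at CpG islands without a promoter, 0.36 at promoters without an island and 0.03 at regions with neither. The medians of the same classes on the control diet were 0.19, 0.18, 0.22 and 0.19. Set against regions of like sham coverage, regions with a CpG island exceeded those without one by 0.26 with TAC on the control diet. With TAC on the BCAA-free diet they did so by 0.75. The sham libraries are also the denominators of these ratios, so this matching can itself tilt the gap. On the control diet the unmatched medians above showed no such gap, and the matched one ran from -0.12 to 0.38 over bins of coverage.

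The largest rises among regions past the coverage filter were at Morc4 (2.54), the immunoglobulin heavy chain locus Igh (2.25), Echdc3 (2.25), Pdgfc (a growth factor gene, 2.20), Ccna1 (2.12), Trim9 (2.11), Rasa2 (2.07), Dock11 (2.06), Hspa1b (inducible HSP70, 2.03) and Hspbp1 (2.02). The Morc4 promoter region (chrX:139870600–139871799) went from 3.94 to 27.8 (21 to 149 tags), and the Hspa1b region, of 199 bp, rests on 5 and 22 tags, with a 95% counting interval of the ratio of 1.63 to 14.9. The largest falls were at Tmem163 (-1.68), Synpo2 (-1.50), Ston2 (-1.49), Slc9a4 (-1.40), Adam22 (-1.34), Otud7b (-1.29), Cdk6 (-1.28), Rbfox1 (-1.24), Nckap5 (-1.24) and Pik3c2g (-1.21). The Synpo2 region (chr3:123226200–123230199), in a gene for an actin-binding Z-disc protein, went from 16.2 to 5.07.

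In sham hearts, the diet without BCAA went with less H3K23pr at endothelial and macrophage genes. Csf1r, the receptor gene that macrophages depend on, fell by 0.83 on the log2 scale, from a coverage of 8.91 on the control diet to 4.56. Aplnr, the apelin receptor gene of endothelium, fell by 0.75, from 11.8 to 6.65. Bckdhb, in BCAA breakdown, rose by 0.85, from 5.22 to 10.2. With a pseudocount of 5 these changes were -0.54, -0.53 and 0.57, all under 1.5-fold.

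The endothelial list lay furthest below matched lists (-0.35, percentile 0), and beside Aplnr the transcription factor genes Sox18 (-0.71) and Sox7 (-0.64) and the von Willebrand factor gene Vwf (-0.66), named after their values were seen, fell. The macrophage list stood at -0.29 (percentile 0.02), with 7 of 18 genes down: Csf1r, the lysozyme gene Lyz2 (-0.71), C1qa, C1qb and C1qc in their shared region (-0.66), Sfpi1 (-0.63) and Aif1 (-0.60), of which all but Csf1r were named after their values were seen. The inflammatory list stood at -0.17 (percentile 0.31), with the chemokine gene Cxcl1 at -0.67 (-0.55 after rescaling to equal totals). These 3 lists stood apart under every alternative run. Fibroblast markers (-0.16, percentile 0.57) and extracellular matrix genes (-0.15, percentile 0.17) lay lower as well, though no gene of either fell 1.5-fold. Averaging all regions of a gene put them at percentiles 3.66 and 4.69.

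Calcium handling (0.16, percentile 99.9), heat shock and oxidative stress (0.14, percentile 99.8), BCAA catabolism (0.12, percentile 99.1), fatty acid oxidation (0.11, percentile 99.8) and oxidative phosphorylation (0.11, percentile 99.9) lay above matched lists. Apart from Bckdhb no gene of these lists rose 1.5-fold. In peak coverage they stood at percentiles 86.5, 92.9, 88.2, 90.1 and 82.6, inside the range of matched lists. Of the fixed genes, Atp2a2 (-0.01), Myh6 and Myh7 (-0.01), Bckdha (-0.02), Pccb (-0.03) and Atf4 (0.08) changed by less than 0.1, and Col1a1 and Nppa by -0.27 each.

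Few regions changed with diet in sham hearts. Of 24476 regions called in either library, 198 were higher and 816 lower, and the median was -0.10. Higher regions made up 19.5% of those past 1.5-fold, 43.8% after rescaling to equal median ratios (366 and 470, a shift of 0.08), 56.8% after rescaling to equal totals (463 and 352, a shift of 0.12) and 58.9% with the trend on coverage removed (458 and 320). The largest rises among regions past the coverage filter were at Antxr1 (0.78), Esco1 (0.76), Psmd6 (0.67), Synpo2 (0.66), Lemd3 (0.66), Ston2 (0.64), Zfand4 (0.63), Tpd52l1 (0.63), Fam133b (0.62) and Terc (0.61). The largest falls were at Pip5k1c (-0.99), Arhgef15 (an endothelial exchange factor gene, -0.98), Slc25a47 (-0.92), Dennd2c (-0.91), Ttc28 (-0.91), Grk1 (-0.91), Ccdc88c (-0.91), Erp27 (-0.90), H2-Q7 (-0.86) and Dlgap1 (-0.84). With a pseudocount of 5, all of these rises but Antxr1 were under 1.5-fold, and Dlgap1 (-0.53) was too. In peak coverage Antxr1 (0.54) and H2-Q7 (-0.57) were under it.

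**Figure D2:**
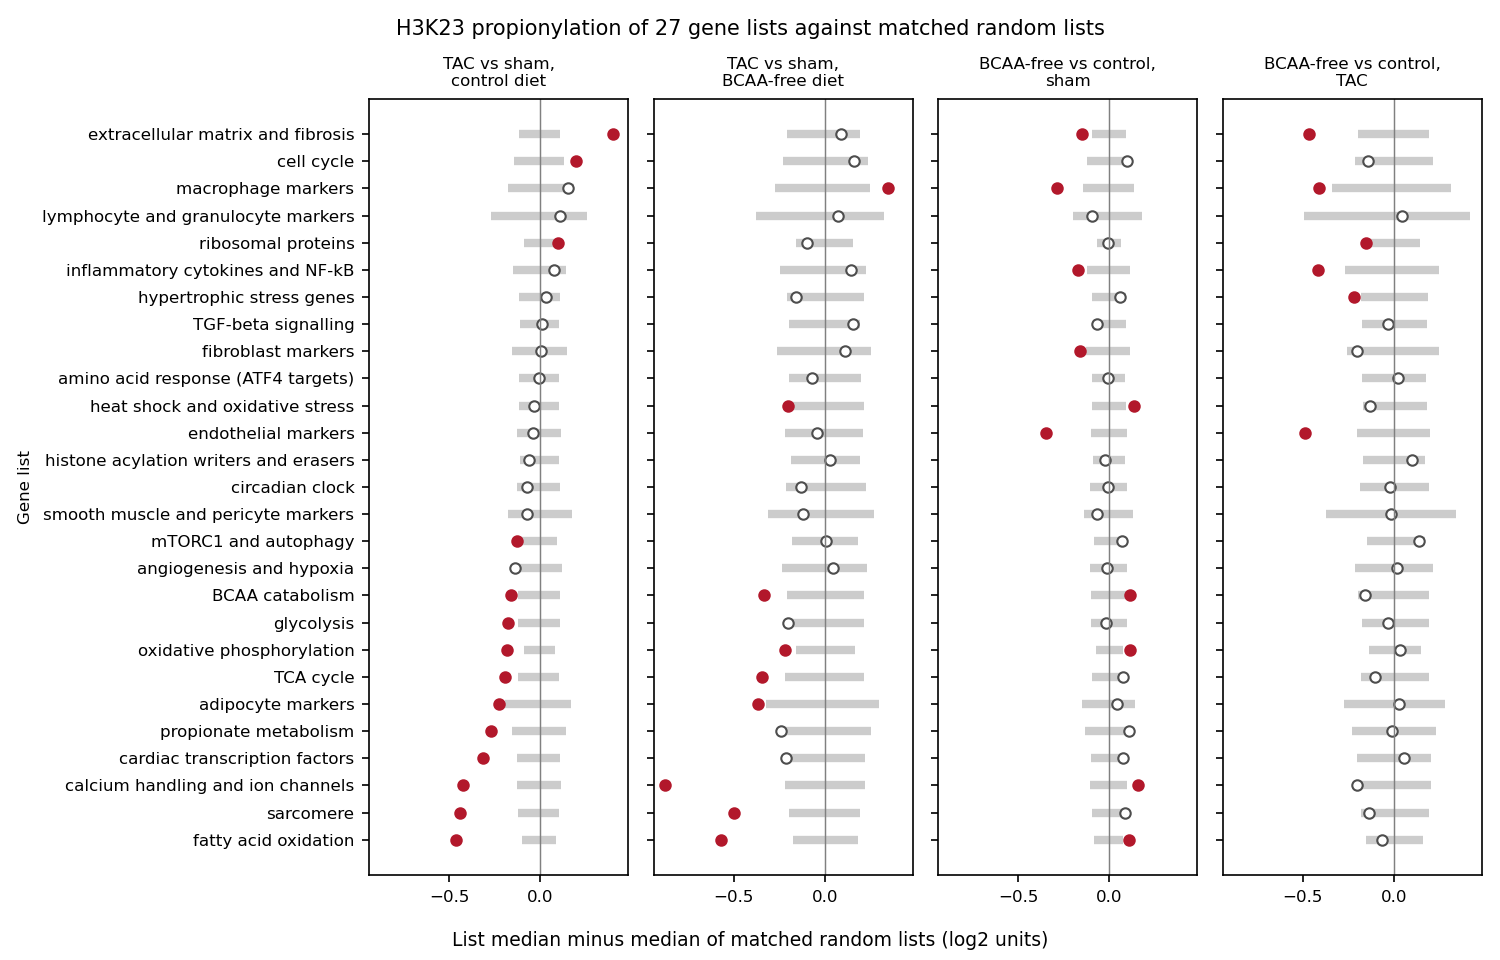
Median log2 ratio of 27 gene lists (rows) minus the median of matched random lists (x axis, log2 units) in the 4 comparisons (panels), with grey bars over the central 95% of the random lists and filled points outside them. The matrix list lay at 0.40 for TAC on the control diet and at -0.47 for diet in TAC hearts, and the endothelial list at -0.35 and -0.49 for diet in sham and TAC hearts.

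In TAC hearts, the diet without BCAA went with less H3K23pr at endothelial, inflammatory and matrix genes, relative to other genes of like coverage. Of these lists only the endothelial one stood apart under every alternative run. CpG islands had more H3K23pr with this diet. Il6, the interleukin 6 gene, fell by 1.42 on the log2 scale, from 15.3 on the control diet to 5.10 on the BCAA-free diet. Il1b, the interleukin 1 beta gene, fell by 1.28, from 8.62 to 2.95. Both genes had risen with TAC on the control diet, so their rises and falls rest on the same control-diet TAC library. Postn fell by 0.95, from 10.3 to 4.86. Suclg2, which encodes a subunit of the enzyme that takes up succinyl-CoA, the end product of propionate breakdown, rose 2.47-fold (log2 1.31), to a coverage of 26.2. The propionate metabolism list (-0.01, percentile 46.6) and the TCA cycle list (-0.10, percentile 12.2) lay inside the range of matched lists.

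The endothelial list again lay furthest below matched lists (-0.49, percentile 0), and it alone stood apart under every alternative run in this comparison. Its genes moved apart: Cd34 changed by -0.59 in mean coverage but by 0.69 in peak coverage, and Flt1, a VEGF receptor gene, rose by 0.66 but by 0.51 after rescaling to equal median ratios. The matrix list stood at -0.47 (percentile 0), where Postn, Tnc, Col5a2 (-0.90), Loxl2 (-0.85), Fap (-0.84) and Thbs1 (-0.64) fell and 0 genes rose, and all but Postn were named after their values were seen. In peak coverage that list stood at -0.13, percentile 13.2. Not set against matched lists, the median changed sign between mean and peak coverage for the matrix list (-0.13 and 0.55), the inflammatory list (-0.07 and 0.28), the endothelial list (-0.13 and 0.40) and the macrophage list (-0.10 and 0.11). The inflammatory list stood at -0.42 (percentile 0.15), and beside Il6 and Il1b the chemokine genes Cxcl2 (-0.63), Ccl4 (-0.63), Cxcl10 (-0.60) and Ccl2 (-0.60), named after their values were seen, fell. The macrophage list stood at -0.41 (percentile 1.03), the hypertrophic stress list at -0.22 (percentile 0.98) and the ribosomal protein list at -0.15 (percentile 1.36). Random lists matched on CpG islands put the inflammatory list at percentile 4.16, the macrophage list at 26.8 and the hypertrophic stress list at 2.91, and averaging all regions of a gene put the ribosomal list at 30.8. None of the 27 lists stood apart on the high side in mean coverage, whereas angiogenesis and hypoxia did in peak coverage (percentile 99.1).

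Of all promoter regions with a CpG island, 36.3% were higher, and single genes at such promoters rose. They included the acetyltransferase gene Kat6b (1.28), the transcription factor gene Foxo1 (1.03), the mTORC1 scaffold gene Rptor (1.04), the fatty acid enzyme gene Acads (0.92), the replication gene Mcm3 (1.37), Bmp4 (1.10) and Vegfa (0.95). The clock gene Clock (1.19), the deacylase gene Sirt1 (1.07) and Acss3 (1.25), an acyl-CoA synthetase gene whose promoter region has no CpG island, were named after their values were seen. Acss3 had changed by -0.69 with TAC on the control diet (-0.44 with a pseudocount of 5). Its fall and its rise both rest on the control-diet TAC library. Asns, which makes asparagine in amino acid shortage, rose by 0.77, but by 0.49 in peak coverage, and Phgdh, in serine synthesis, by 0.81. With the trend on coverage removed within regions with and without a CpG island, Foxo1 (0.58), Acads (0.53), Vegfa (0.50), Asns (0.39) and Phgdh (0.21) were under 1.5-fold. Slc7a11, the cystine transporter gene of the same response, fell by 1.63, from 7.74 to 1.82 (76 to 18 tags). It had risen by 1.47 with TAC on the control diet, from 2.15, against the same control-diet TAC library, so both values rest on that library.

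By class, promoters with a CpG island had a median of 0.45, CpG islands without a promoter 0.52, promoters without an island -0.08 and regions with neither -0.31. Of the 31645 regions called in either TAC library, 5561 were higher and 5556 lower, with a median of 0.02. Rescaling to equal median ratios shifted the median by -0.14 and gave 3751 higher and 7458 lower (33.5% higher instead of 50.0%), and equal totals shifted it by -0.11 and gave 4104 and 7027 (36.9%). Peak coverage gave 10764 and 6169 (63.6%), and removing the trend on coverage gave 5015 and 3137 (61.5%). Among regions called in all 4 libraries, 2698 were higher and 610 lower. The ratio rose with coverage, from -0.59 in the lowest to 0.40 in the highest decile of regions. The largest rises among regions past the coverage filter were at Echdc3 (2.52), Rimkla (2.38), Hspbp1 (2.19), Rgs17 (2.04), Wdr1 (1.98), Wnt3a (1.96), Rasa2 (1.95), Bnc2 (1.95), Alk (1.93) and Cpeb3 (1.92). The largest falls were at Pam (-1.41), Vps8 (-1.39), Wdr95 (-1.32), Tmem154 (-1.26), Gas2 (-1.24), Wdr67 (-1.23), Lekr1 (-1.23), Tll1 (-1.22), Arhgap24 (-1.21) and Xrcc5 (-1.21). The Rimkla promoter region (chr4:119492000–119493199) went from 3.50 to 22.4, and the Pam region (chr1:97831800–97835799), 261833 bp into the gene of a peptide-amidating enzyme, from 18.7 to 6.42.

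**Figure D3:**
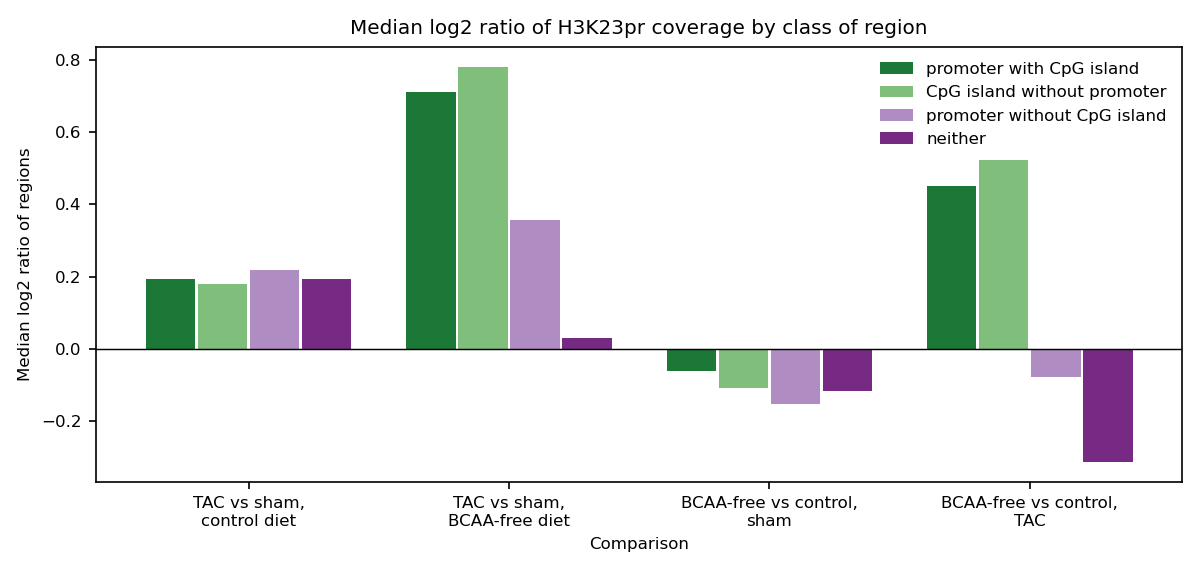
Median log2 ratio (y axis) of regions grouped by promoter and CpG island content (bars) in the 4 comparisons (x axis). With TAC on the BCAA-free diet the medians ran from 0.03 at regions with neither to 0.78 at CpG islands without a promoter, against 0.18 to 0.22 with TAC on the control diet.

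**Figure D4:**
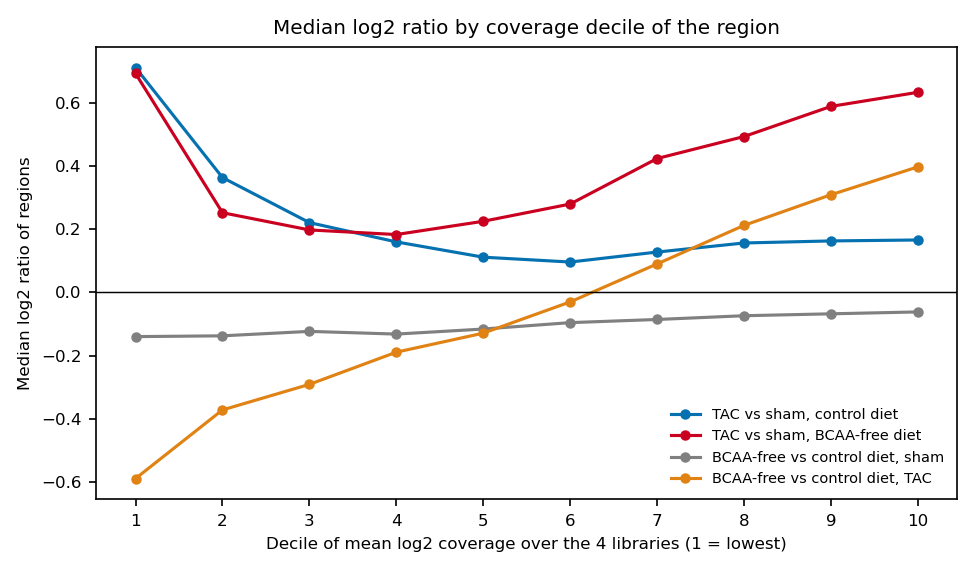
Median log2 ratio (y axis) by decile of mean log2 coverage over the 4 libraries (x axis, lowest first), with a line per comparison. For diet in TAC hearts the median climbed from -0.59 to 0.40, and for TAC on the control diet it stood at 0.71 in the lowest and 0.17 in the highest decile.

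The TAC responses on both diets were set side by side, and the diet responses after both operations. Col1a1 rose with TAC by 1.05 and 1.18, Col12a1 by 1.16 and 1.45, Fn1 by 1.02 and 1.31, and Lox by 0.95 and 1.10 on the control and the BCAA-free diet. Tnc rose by 1.54 on the control diet, had no called region in either BCAA-free library, and its TAC effect on the BCAA-free diet was lower by 1.44 (a difference of -1.44). Postn differed in the same way by -0.71, Loxl2 by -0.85, Thbs1 by -0.67 and Col5a2 by -0.65. Ryr2 differed by -0.83 and Bckdhb by -1.39, while Kat6b differed by 1.45, Foxo1 by 1.08 and the endothelial gene Sox7 by 1.02. These differences could not be tested with 1 library per group. Fn1, Lox, Loxl2, Thbs1 and Col5a2 were named after their values were seen.

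Over all 34346 regions the TAC effects on both diets correlated at r 0.36 (Spearman 0.35), regions not being independent replicates and the compared libraries being different ones. Regions higher on both diets numbered 1826, against 1726 from independent lists of these sizes, and regions lower on both numbered 683 against 134. Among regions without a CpG island 1357 were higher on both against 847, and among those with one 469 against 356. The diet effects in sham and TAC hearts correlated at r 0.19 (Spearman 0.20), with 84 regions higher in both against 45.8 and 423 lower in both against 215. Of the 280 regions higher with the diet in sham hearts, 49 were lower in TAC hearts and 48.2% kept their sign. Of the 41 with a CpG island 33 were higher in TAC hearts too, against 15.2 from independent lists. Of the 239 without one 51 were, against 15.6. The matrix list, high with TAC on the control diet and low with the BCAA-free diet in TAC hearts, was measured against the same control-diet TAC library in both, so those results are not independent. Likewise, the diet in sham hearts and TAC on the BCAA-free diet share the BCAA-free sham library, so the opposite changes of the macrophage list (-0.29 and 0.35), the BCAA catabolism list (0.12 and -0.34), the calcium handling list (0.16 and -0.88) and Bckdhb (0.85 and -1.15) are not separate results. The rise at CpG islands with TAC on the BCAA-free diet and with the diet in TAC hearts rests in both on the BCAA-free TAC library.

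As a difference of the TAC effects, BCAA-free minus control diet, 7290 regions were higher and 4312 lower by 1.5-fold, with a median of 0.12 and 62.8% higher. Rescaling to equal median ratios gave 3984 and 7069 (36.0%), equal totals 3894 and 7269 (34.9%), and removing the trend on coverage 4104 and 5909 (41.0%). Among regions called in all 4 libraries, 3631 were higher and 410 lower. Relative to matched lists, 8 lists lay low: calcium handling (-0.42), inflammatory genes (-0.34), extracellular matrix (-0.31), BCAA catabolism (-0.30), heat shock and oxidative stress (-0.24), fatty acid oxidation (-0.22), hypertrophic stress (-0.22) and ribosomal proteins (-0.17). None of the lists lay high, except the macrophage list (percentile 97.6) when random lists were matched on CpG islands. This contrast of lists was added after the data had been seen. The same matching put the inflammatory list (percentile 5.11) and the hypertrophic stress list (2.73) back inside the range.

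Among genes that the diets touch directly, the BCAA catabolism list stood apart in 3 of the 4 comparisons, low with TAC on the control diet (1 of 23 genes up) and on the BCAA-free diet (5 up, 1 down) and high with the diet in sham hearts (1 up). Only the result for TAC on the control diet held under every alternative run. In peak coverage the other results came to percentiles 3.73 (TAC on the BCAA-free diet) and 88.2 (diet in sham hearts), and both rest on the BCAA-free sham library. Bckdha, a subunit gene of the branched-chain dehydrogenase, stayed under 1.5-fold in all 4 comparisons, from -0.34 for TAC on the BCAA-free diet to -0.02 for diet in sham hearts. Its kinase gene Bckdk rose by 0.73 with TAC on the BCAA-free diet, as deposited. Pcca and Pccb, which encode propionyl-CoA carboxylase, stayed under 1.5-fold throughout, with Pcca at -0.56 for diet in sham hearts and 0.51 in TAC hearts, read from different regions. Bcat1, an aminotransferase gene, rose by 0.85 and the short-chain fatty acid receptor gene Ffar2 by 0.95 with TAC on the control diet, but with a pseudocount of 5 by 0.53 and 0.48, and with the trend on coverage removed Ffar2 rose by only 0.10. Abat, the aminotransferase gene of a route into propionate metabolism, rose by 1.20 with TAC on the BCAA-free diet and by 1.15 with the diet in TAC hearts, though by 0.45 in the former with the trend on coverage removed within CpG island classes. The propionate list, which stood apart for TAC on the control diet (-0.27, percentile 0.08), lay at -0.24 for TAC on the BCAA-free diet (percentile 3.19, but 0.77 when all regions of a gene were averaged and 1.19 when matched on CpG islands), 0.11 for diet in sham hearts (percentile 95.6) and -0.01 for diet in TAC hearts (percentile 46.6).

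The amino acid response list stayed within the range of matched lists in all 4 comparisons, at differences of -0.01, -0.07, -0.00 and 0.02 in the order used above. With TAC on the control diet its extremes were Slc7a11 (1.47) and Cth, a cysteine synthesis gene (-0.74). Atf4, its regulator gene, ran from 0.08 to 0.42. Fgf21, a stress hormone gene, rose by 1.00 with TAC on the control diet at a region 9791 bp from its start, from 2.86 to 6.70, by 0.57 with a pseudocount of 5 and by 0.15 with the trend on coverage removed. For TAC on the control diet, the other lists inside the range were TGF-beta signalling (0.01, percentile 59.4, but 99.6 when all regions of a gene were averaged), circadian clock (-0.07, percentile 12.4, but 2.48 when averaged), histone acylation writers and erasers (-0.06, percentile 12.8), angiogenesis and hypoxia (-0.14, percentile 2.54, but 1.07 to 2.42 and so apart under 6 alternatives), smooth muscle and pericyte markers (-0.07, percentile 20.6), lymphocyte and granulocyte markers (0.11, percentile 79.8), fibroblast markers (0.01, percentile 53.5), endothelial markers (-0.04, percentile 24.96) and heat shock and oxidative stress (-0.03, percentile 28.9). Cardiac transcription factors with TAC on the BCAA-free diet (-0.21, percentile 2.85) stood apart under 7 alternatives, at percentiles of 0.03 to 2.40. Over the 4 comparisons 39 of 108 list results stood apart, and 16 of these 39 did so on the same side under every alternative run.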

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

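The regions below moved one way in one setting of the study and the opposite way in the other, each by at least 1.5-fold. The differences were not tested, since each group had 1 library.

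A 599-bp region in Rasa2 (chr9:96544000–96544599), a gene for a Ras GTPase-activating protein, changed by -0.81 with TAC on the control diet and by 2.07 with TAC on the BCAA-free diet. With the diet it changed by -0.92 in sham hearts and by 1.95 in TAC hearts. Its coverage was 8.68 in control-diet sham, 4.53 in control-diet TAC, 4.11 in BCAA-free sham and 20.4 in BCAA-free TAC hearts, and it lies 87204 bp from the gene's start. A 199-bp region of Hspa1b (chr17:34957000–34957199), the inducible HSP70 gene, changed with the diet by -0.71 in sham hearts and by 1.05 in TAC hearts, with coverages of 9.33, 11.5, 5.33 and 24.8 in the same order of groups. Both regions are short and rest on few tags: 23, 12, 11 and 54 for Rasa2 and 8, 10, 5 and 22 for Hspa1b. The 95% counting interval of the tag ratio included 1 for each fall (0.237 to 1.09 and 0.210 to 1.02 for Rasa2, 0.161 to 2.17 for Hspa1b) and reached 1.00 for the rise of Hspa1b, so these opposite directions are not beyond counting error. The rises of Rasa2 had intervals of 2.54 to 10.4 and 2.38 to 9.24.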

How the results depend on the processing

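Removal of the trend on coverage (also within regions with and without a CpG island), the promoter and CpG island subsets and the matching on CpG islands were chosen after the data had been seen. The other alternatives were planned. No paired analysis was possible because each group had 1 library. Comparisons are given in the order TAC on the control diet, TAC on the BCAA-free diet, diet in sham hearts, diet in TAC hearts and difference of the TAC effects. Values that moved beyond the range set for them are given by comparison, and where no cause follows from how an alternative is built, the cause was not tested.

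In peak coverage, TAC on the control diet gave 2618 lower regions and a median of 0.19, TAC on the BCAA-free diet a median of 0.63, diet in sham hearts 745 higher, 2440 lower and -0.082, diet in TAC hearts 10764 higher and 0.21, and the difference 12747 higher. Direction turned for Myocd (0.029) and Ttn (0.038) with TAC on the BCAA-free diet, for Cd34 (0.69) with diet in TAC hearts and for the mTORC1 and autophagy list (0.016) with TAC on the control diet.

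Rescaling moves the ratios of a comparison by about the same amount, less at low coverage because of the pseudocount, which by construction shifts the counts. With equal median ratios, TAC on the control diet gave 2230 lower and a median of 0.071, TAC on the BCAA-free diet 4752 higher, 5322 lower and 0.078, diet in sham hearts 366 higher, 470 lower and -0.014, diet in TAC hearts a median of -0.12, which turned direction, and the difference 3984 higher and 7069 lower. With equal totals the values were 2096 lower and 0.087, then 4861 higher, 5275 lower and 0.084, then 463 higher, 352 lower and a median of 0.024, which turned direction, then a median of -0.091, which turned too, then 3894 higher and 7269 lower.

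A pseudocount of 0.1 gave medians of 0.21 and 0.46 for TAC on the control and the BCAA-free diet, and 319 higher, 1334 lower and -0.105 for diet in sham hearts. A pseudocount of 5 shrinks ratios by construction. It gave 1772 higher, 321 lower and 0.14, then 6665 higher, 927 lower and 0.30, then 37 higher, 77 lower and -0.070, then 3265 higher and 2078 lower, then 4232 higher and 1604 lower.

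Over all merged regions the medians were 0.17 and 0.31 for TAC on the control and the BCAA-free diet, diet in sham hearts gave 1275 lower and -0.10, and diet in TAC hearts -0.0054, which turned direction. Regions called in all 4 libraries gave 646 higher, 323 lower and 0.13, then 5468 higher, 605 lower and 0.39, then 4 higher, 162 lower and -0.082, then 2698 higher, 610 lower and 0.17, then 3631 higher and 410 lower. The smaller region set limits these counts, but its size alone does not set the split of higher and lower regions. For diet in TAC hearts the split had been 5561 higher and 5556 lower, and for the difference 7290 and 4312. This setting leaves out every region that was not called in some library. A 2-fold threshold gave 1229 higher and 175 lower, then 3797 and 535, then 16 and 37, then 1581 and 1488, then 2110 and 1204. Requiring every library to lie above the median coverage of called regions left 6759 regions called in all 4 libraries instead of 15417.

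Removing the trend sets the medians to 0.00 by construction. It gave 1605 higher and 2912 lower, then 3645 and 5372, then 458 and 320, then 3137 lower for diet in TAC hearts and 4104 higher for the difference, and Fgf21 with TAC on the BCAA-free diet turned to -0.10. Removing it within regions with and without a CpG island gave 1740 and 2599, then 3277 and 3960, then 481 and 300, then 3611 and 2275, and 3799 higher for the difference. Mef2c with TAC on the control diet turned to -0.0059 and Pax5 with diet in TAC hearts to -0.15.

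Promoter regions alone gave 1088 higher and 176 lower for TAC on the control diet, 222 lower and a median of 0.64 for TAC on the BCAA-free diet, 29 higher, 197 lower and -0.078 for diet in sham hearts, 612 lower and 0.35 for diet in TAC hearts and 412 lower for the difference. Regions without a promoter gave 3336 higher and 0.10 for TAC on the BCAA-free diet, -0.12 for diet in sham hearts, 1602 higher and -0.28 for diet in TAC hearts, which turned direction, and 2412 higher for the difference.

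Of 348 results of named genes, 195 passed 1.5-fold, 93 of these were under 1.5-fold in at least 1 alternative and 6 changed sign. Of 39 list results that stood apart, 23 did not under at least 1 alternative, and 22 results inside the range of matched lists stood apart under at least 1, most often cardiac transcription factors with TAC on the BCAA-free diet (7) and angiogenesis and hypoxia with TAC on the control diet (6). Alternatives that subtract the input, leave out regions strong in it or require signal above it were not run, since the input was not analysed here. Depth limits the short regions most: at the Knstrn region, with 25 and 79 tags, the 95% counting interval of the ratio ran from 1.99 to 5.17.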

Other observations

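The tests of the matrix pattern and of the endothelial and macrophage pattern below were chosen only after the result was seen, as was the contrast of lists between diets.

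In TAC hearts, promoter regions were higher and other regions lower on the BCAA-free than on the control diet. Promoters exceeded other regions of like sham coverage by 0.57. This value does not decide whether a higher signal over background in the BCAA-free TAC library was the cause. Mean and peak coverage were matched separately, so regions matched on one could differ in the shape of their peaks. The BCAA-free TAC library had the steepest peaks (90th percentile of peak coverage 149). A CpG or GC bias of that library cannot be told apart from biology. The bound set for it beforehand was passed, since promoters without a CpG island exceeded other regions without one by 0.19, above 0.1, but that bound was wrong: only the presence of an island is known, GC content was not matched, and among island regions promoters exceeded others by only 0.05. An effect of the diet under pressure overload stays open, untested, with 1 library per group.

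With TAC on the control diet, matrix genes were higher and heart muscle genes lower. The matrix list exceeded the endothelial list by 0.45 (random pairs of lists -0.16 to 0.17). The 7 lists of matrix and cell markers spread over 0.64 (percentile 99.9 of random sets). Neither value decides whether a larger share of all non-myocyte nuclei was the cause. The matrix list prompted the question and is the top of that spread, whereas random lists were not chosen for their values. The endothelial list itself lay inside the range of matched lists (-0.04, percentile 24.96). The matrix list exceeded the fibroblast marker list by 0.40 (random pairs -0.18 to 0.19). A larger share of fibroblast nuclei stays open all the same. The test took both lists to move equally, which fibroblasts in a changed state need not do. After removal of a trend on coverage the matrix list lay 0.47 above matched lists. This removal could not decide, because the distance before it (0.40) was already one from lists of like coverage. A changed state of fibroblasts after pressure overload may explain it, as a hypothesis, and was not tested.

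In sham hearts, endothelial and macrophage genes were lower on the BCAA-free diet. The endothelial and the smooth muscle and pericyte lists differed by -0.26 (random pairs -0.14 to 0.18). The 6 lists of cell markers spread over 0.39 (percentile 99.4 of random sets). Neither value decides whether a smaller share of all non-myocyte nuclei was the cause. The endothelial list prompted the question and is the bottom of that spread, whereas random lists were not chosen for their values. A smaller share stays open, since the fibroblast (-0.16) and matrix (-0.15) lists were low. The calcium handling, fatty acid oxidation and oxidative phosphorylation lists were high. After removal of a trend on coverage the endothelial list differed from matched lists by -0.33. This removal could not decide, because the difference before it (-0.35) was already one from lists of like coverage. Fewer endothelial and macrophage nuclei in that pool, or a diet effect on these cells, may explain it, as hypotheses that were not tested.

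The broadest region covered Ablim1, a gene for an actin-binding protein of muscle (chr19:57067800–57319599, 251799 bp, mean coverage 17.5), followed by Tns1 with Rufy4 (226199 bp) and Zbtb16 (197599 bp). The basement membrane collagen genes Col4a1 and Col4a2 share a region of 180399 bp, which changed by 0.47 with TAC on the control diet and by -0.48 with the diet in TAC hearts, both under 1.5-fold. The highest coverage lay at a region with no listed gene (chr9:124422400–124427599, 70.8), then at Txnip with Polr3gl (52.1) and Armc12 (52.1). Short regions had higher median ratios with TAC: 0.42 in the shortest and 0.10 in the longest quintile on the control diet, and 0.74 and 0.31 on the BCAA-free diet. Because a region enters a comparison by being called in 1 of its libraries, selection can tilt these medians. Regions on the X chromosome and on autosomes had like medians, 0.18 and 0.20 with TAC on the control diet and 0.08 and 0.02 with the diet in TAC hearts.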
